A study of Escherichia coli with 59 samples.

How the data were processed

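RNA of Escherichia coli K12 substrain W3110 was sequenced after depletion of ribosomal RNA. Per the labels, cells grew in an ammonia-limited chemostat in a stirred tank reactor (STR), to which a plug-flow reactor (PFR) was later connected as a recycle loop. The 59 libraries came from the STR or from 3 ports along the PFR, P1, P3 and P5, and form 31 groups by port and time. Of these groups, 28 hold 2 libraries and 3 hold 1. The RNA was isolated with a column kit for longer RNAs, with a DNase step, per the labels.

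The deposited raw table holds read counts per gene and library made by the authors. According to the submitters' processing notes, reads were handled with bcl2fastq, cutadapt 1.8.3, STAR 2.4.2a and HTSeq 0.6.1. The genome build and annotation are not given in the sources used here, nor is the strand setting of the counting, so values of leader genes and of genes that overlap others are uncertain in that respect. A filtered table of the authors has the same counts for 3889 of the 4319 gene names. It lacks 108 rRNA and tRNA genes, 8 genes whose names start with sec, and 314 others with low counts. Gene names were matched to the RefSeq annotation of strain MG1655 (assembly ASM584v2) for names and RNA classes alone. Of the names, 3648 equalled a current symbol, 650 matched through 1 synonym and 21 had no match.

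Total counts per library ran from 3576475 to 12918208, with a median of 9465812. The analysis started from the raw table in R 4.3.3. Genes were filtered with filterByExpr by group, which removed 66 and left 4253. Libraries were scaled with TMM, and all 59 were fitted together in edgeR 4.0.16 with 1 mean per group and 28 residual degrees of freedom (estimateDisp, glmQLFit, glmQLFTest). The common biological coefficient of variation was 12.8%. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. CPM stands for a count divided by the TMM-scaled library size, on the usual scale of that unit. Errors are standard errors (SE) of fitted log2 differences or standard deviations (SD) of CPM. Each SE was derived from the test, as the absolute log2 difference divided by the square root of its F statistic.

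The comparisons were P5 minus STR averaged over the 8 times with both replicates at both places, and at each of those times; each port minus STR, and port minus port, averaged over the 3 times with every port; 3 windows of STR times minus the reference state, and each of 11 STR times minus it; the difference between the late and the early P5 response; and the 3 reference samplings among each other. The early window was 5, 10, 25 and 45 min, the middle window 75, 120, 210 and 330 min, and the late window 25, 26 and 28 h.

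Fixed lists of genes by function, 37 in number, were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation. Their p-values were adjusted over the lists of a comparison. Counts of list members that passed are given over all genes tested and adjusted over the list alone. Of the 745 list genes, 741 were in the table. The rule for named genes takes the 10 largest rises and the 10 largest falls for P5 minus STR and for the late window, and 5 of each for the difference between responses. These had to pass the threshold, reach a mean of 10 CPM and have the same sign in both replicates taken alone. From each list described it takes up to 4 passing members by smallest p, or the 2 most abundant where fewer than 2 pass. The genes glnA, glnK, amtB, nac, glnG, gltB, gdhA, relA, spoT and rpoS are always named, and rRNA genes never by size. The comparisons, lists, rule and first set of alternatives were chosen before the data were examined. Genes outside the rule are marked in the text as chosen after their values were seen.

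Shares of counts were compared between P5 and STR with a two-sided permutation test within times (100000 permutations). The alternatives were RLE size factors, total counts without TMM, DESeq2 1.42.0, no filter on low counts, a minimum mean of 10 CPM, the filtered table, no rRNA and tRNA genes, the replicate number as an added term, a fit to the libraries of the comparison alone, each library or replicate number left out, and reference 3 alone as the reference state.

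The pipeline was tested on simulated data with the design and depths of these libraries. Counts were drawn independently for each library, and only a small part of the genes was changed, in both directions. The simulation therefore cannot test the choice of scaling or effects shared between libraries. For P5 minus STR over 8 times it recovered 86% of 50 genes changed 1.25-fold and 100% of those changed 1.5-fold, with 8 false calls among 4036 unchanged genes. For the late window it recovered 58% at 1.25-fold and 98% at 1.5-fold. At a single time, 25 min, it recovered 14% at 1.25-fold and 86% at 2-fold. The p-values measure only the spread between these samples: the labels do not say whether replicates 1 and 2 came from separate cultivations, and samples of 1 cultivation over time are repeated samples.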

Results

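The series follows the transcriptome of an ammonia-limited Escherichia coli culture before and after a plug-flow loop was added to its chemostat, so that cells circulated between the tank and the loop. The reference state in the STR was sampled 3 times before the loop was added (6 libraries), and the STR 11 times afterwards (22 libraries), from 5 min to 28 h. P5 was sampled at the same 11 times (19 libraries), with 1 library each at 75 min, 330 min and 26 h. P1 and P3 were sampled at 25 min, 120 min and 28 h (6 libraries each). Total counts ran from 3576475 to 12918208 per library. The lowest belongs to P5 at 45 min, replicate 2, in which rRNA genes took 9.75% of the counts, against at most 0.37% in any other library. Within groups, Pearson correlations of log CPM across genes ran from 0.979 to 0.996; genes are not independent replicates.

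The first comparison asks how cells that had passed down the loop to P5 differed from cells in the STR at the same times. At P5 the tryptophan genes trpL, trpE and mtr, most general stress genes and part of the nitrogen scavenging genes were higher. Most genes for tRNAs and some flagellar genes were lower. Ribosomal protein genes moved both ways, with 22 higher and 19 lower of 54. The largest rise was that of trpL, the leader peptide gene of the tryptophan operon, at 147 ± 44.7 CPM at P5 and 17.9 ± 3.73 in the STR (SD, n = 16 each). It was 8.02-fold higher (log2 3.00 ± 0.06 SE, adjusted p = 1.93e-28), in 16 of 16 pairs of libraries of 1 time and replicate number. The kinase gene udk, which recycles uridine and cytidine, was 4.28-fold lower, at 25.0 ± 2.85 against 107 ± 11.3 CPM (log2 -2.10 ± 0.04, adjusted p = 3.18e-29), in 16 of 16 pairs.

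Of 4253 genes, 2718 passed (63.9%), 1425 of them higher and 1293 lower at P5, of which 27 and 124 differed at least 2-fold. With total counts in place of TMM, 604 were higher and 1893 lower, and that scaling moved the median of all genes by -0.16 on the log2 scale. Directions of small differences are relative to the typical gene. At single times, 1010 to 1679 genes passed, most at 25 h, where 739 were higher and 940 lower. At 25 h 295 genes were at least 2-fold lower, against 101 to 165 at the other times. Replicate 1 of the STR at 25 h had raised counts of genes with a median under 1 CPM (mean 1.83 CPM). This bears on weakly expressed genes at that time. With total counts, lower genes far outnumbered higher ones at single times as well. Fitted to the 4 libraries of each time alone, 135 passed at 210 min, 420 at 5 min, 523 at 25 min, 527 at 120 min, 590 at 45 min, 963 at 10 min, 1094 at 25 h and 1715 at 28 h.

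**Figure D1:**
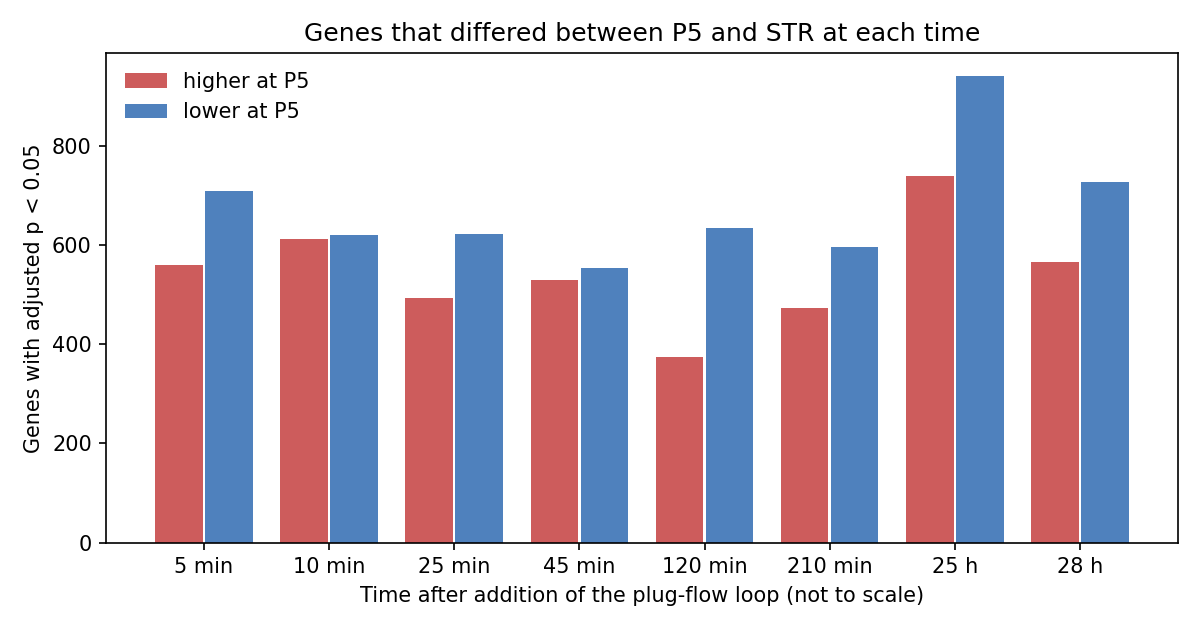
Number of genes with an adjusted p under 0.05 at P5 against the STR (vertical axis) at each of the 8 matched times (horizontal axis, not to scale), with genes higher at P5 in red and lower in blue. Counts of lower genes run from 554 to 940 and exceed those of higher genes at all 8 times with this scaling and the fit to all libraries.

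Among the largest rises after trpL were mtr, a tryptophan permease (3.86-fold, log2 1.95 ± 0.04), and trpE, the first enzyme of tryptophan synthesis from chorismate (3.49-fold, adjusted p = 4.45e-27). The others were ynfM, a predicted transporter (log2 1.75 ± 0.07), yjbA, now psiE (1.49 ± 0.07), glnK, a PII signalling protein (1.39 ± 0.09), ddpX, a dipeptidase (1.30 ± 0.13), the small RNA gene rybA (1.27 ± 0.06), asnA, the ammonia-dependent asparagine synthetase (1.12 ± 0.15), and hisG, the first enzyme of histidine synthesis (1.07 ± 0.06). All had adjusted p-values of 5.32e-08 or smaller. The fixed list of tryptophan and aromatic amino acid synthesis, with 10 genes higher and 6 lower of 18, did not pass (adjusted p = 0.0761), the same counts as adjusted over the list alone; with total counts 3 were higher and 8 lower. Of the 10 largest falls, 8 were tRNA genes, led by leuQ (4.87-fold lower, log2 -2.29 ± 0.16), leuT, leuV, hisR and tyrT. The others were udk and rnpA, the protein part of the enzyme that matures tRNA (4.24-fold lower, log2 -2.08 ± 0.05). Copies of tRNA genes such as leuQ, leuT and leuV share sequence, so the split of reads among them is uncertain.

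**Figure D2:**
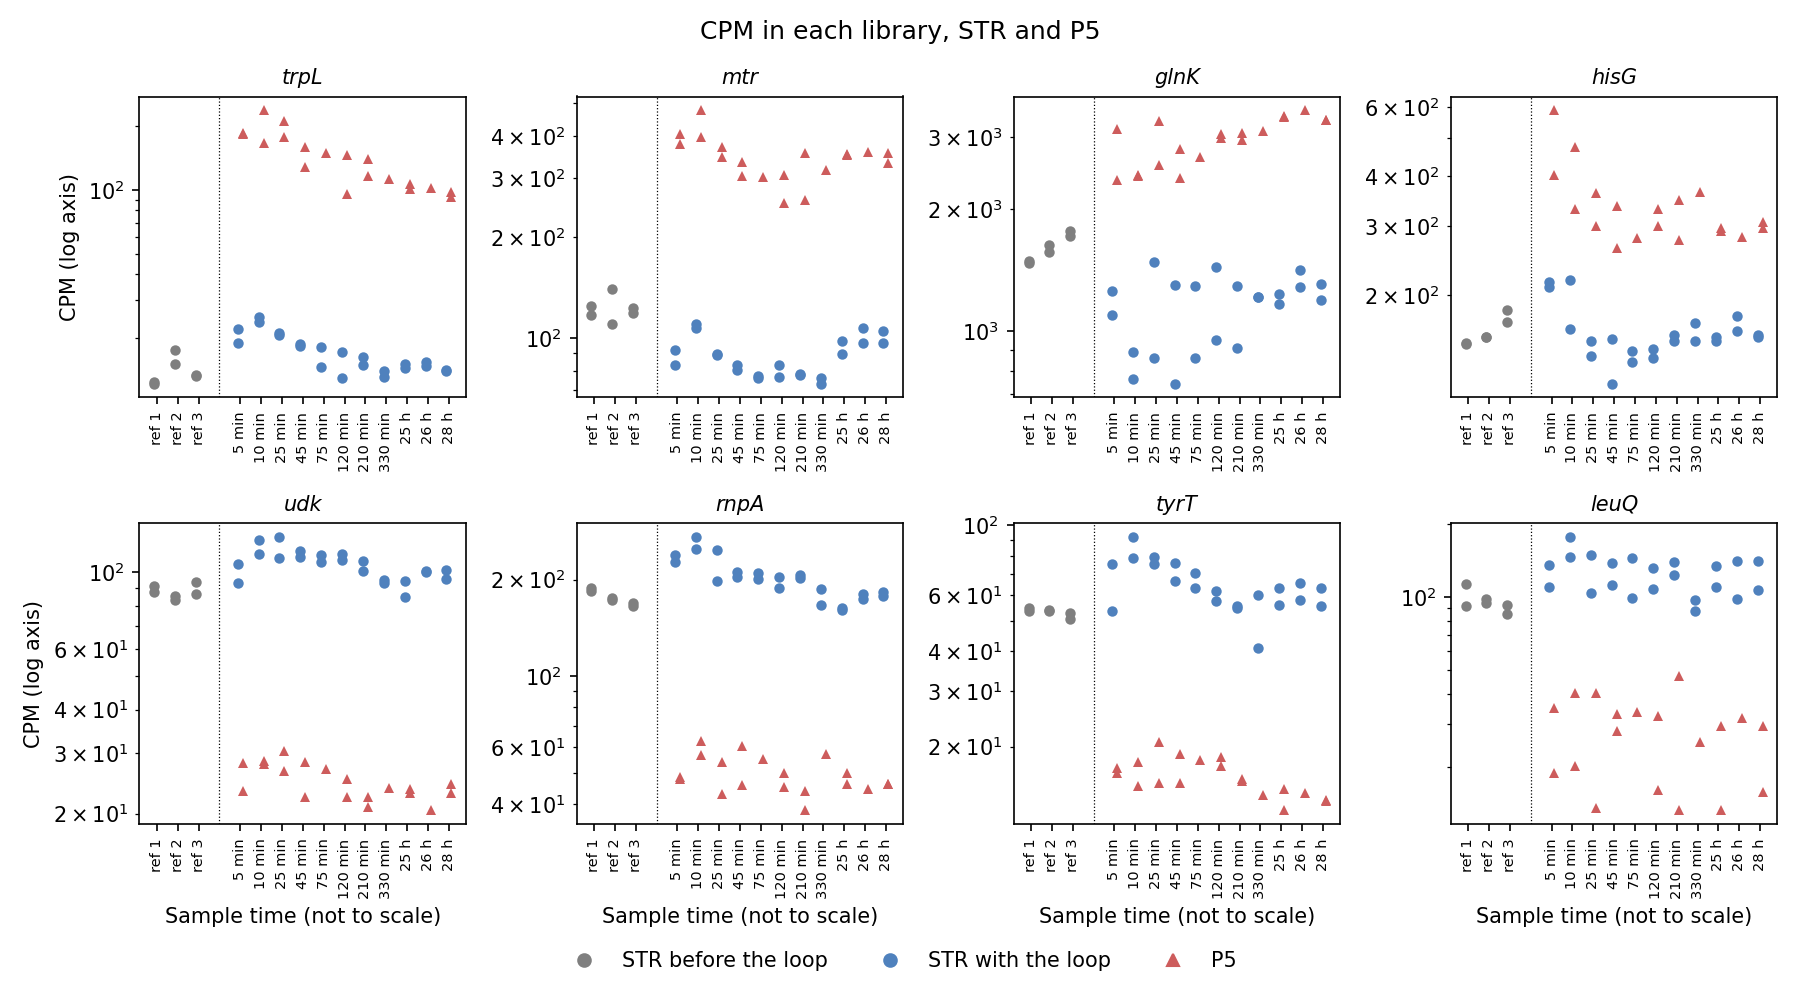
CPM on log axes of genes higher or lower at P5 (vertical axis) by sample time (horizontal axis, not to scale), with P5 and STR libraries as separate points. Points for trpL lie near 147 CPM on average at P5 and near 17.9 in the STR, and those for udk near 25.0 and 107.

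Part of the genes that cells use when ammonia is short rose. Of the 50 genes of the NtrC and Nac regulon, which serve nitrogen scavenging, 22 were higher and 5 lower, the same counts as adjusted over the list alone. Of all 4253 genes, 1425 were higher and 1293 lower. The list passed (adjusted p = 0.0241), but not with an estimated correlation (adjusted p = 0.922 with an estimated correlation). With total counts 15 were higher and 8 lower. The glutamine transporter gene glnH (2.02-fold, log2 1.02 ± 0.06), the arginine catabolism gene astC (2.06-fold, 1.04 ± 0.07), the regulator gene nac (2.09-fold, 1.06 ± 0.13) and glnA, for glutamine synthetase (1.81-fold, 0.85 ± 0.10), rose. So did the ammonium channel gene amtB (1.60-fold, 0.68 ± 0.09), whereas glnG, for the regulator NtrC, differed by 0.16 ± 0.10 (adjusted p = 0.148). Glutamate synthase gene gltB and glutamate dehydrogenase gene gdhA were each higher by 0.24, and with total counts neither passed (adjusted p = 0.193 and 0.232).

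Some lists of stress genes passed and others did not. Of 31 genes of the general stress response under RpoS, 29 were higher and 2 lower (adjusted p = 3.22e-05, and adjusted p = 0.848 with an estimated correlation), also as adjusted over the list alone; 17 and 2 with total counts. Members were yhiO, now uspB (log2 1.03 ± 0.05), osmE (0.77 ± 0.04), uspA (0.65 ± 0.04) and the morphology gene bolA (0.74 ± 0.05), and rpoS itself rose by 0.47 ± 0.04. Of 14 genes of ribosome hibernation and the stringent response, 12 were higher and 2 lower (adjusted p = 0.0335), led by yfiA, now raiA, which binds idle ribosomes (0.97 ± 0.07), and rsd (0.55 ± 0.05). Among them relA, which makes the alarmone ppGpp, rose by 0.32 ± 0.06, and spoT, which also degrades it, fell by 0.35 ± 0.03. Heat shock genes were higher in 15 and lower in 2 of 21 (adjusted p = 0.0122; rpoH 0.63 ± 0.05, the protease gene clpP 0.45 ± 0.03), and oxidative stress genes in 15 and 1 of 17 (adjusted p = 0.0122; sufA 0.63 ± 0.05, the superoxide dismutase gene sodA 0.38 ± 0.04). Over each of these lists alone the counts were the same. With an estimated correlation none of these passed (each adjusted p = 0.848 with an estimated correlation), and with total counts hibernation, heat shock and oxidative stress did not pass (adjusted p = 0.0992, 0.0625 and 0.057).

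The acid resistance list, with 7 higher and 2 lower of 13 (adjusted p = 0.536), the envelope stress list, with 15 higher and 4 lower of 19 (adjusted p = 0.0638), the SOS list, with 11 and 3 of 17 (adjusted p = 0.109), and the cold shock list, with 5 and 1 of 10 (adjusted p = 0.603), did not pass. Over each list alone the counts were the same, and with total counts they were 2 and 3, 11 and 4, 5 and 5, and 0 and 4.

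In metabolism, branched-chain amino acid synthesis was higher in 12 and lower in 1 of 13 genes (adjusted p = 0.00781), with ilvB at 0.68 ± 0.06 and ilvC at 0.62 ± 0.05. The pentose phosphate list was higher in 9 of 9 (adjusted p = 0.0122; talB 0.33 ± 0.02, gnd 0.23 ± 0.02). The citric acid cycle list was higher in 16 and lower in 2 of 19 (adjusted p = 0.0241), with icd at 0.34 ± 0.03 and sdhC, for a membrane subunit of succinate dehydrogenase, at -0.86 ± 0.04. Each had an adjusted p = 0.848 with an estimated correlation and the same counts adjusted over the list alone. With total counts the pentose phosphate and citric acid cycle lists did not pass (adjusted p = 0.1 and 0.108). Histidine synthesis had 7 of 8 genes higher but did not pass as a list (adjusted p = 0.0634).

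Genes of growth and motility moved both ways. Of 54 ribosomal protein genes, 22 were higher and 19 lower (list adjusted p = 0.711), as adjusted over the list alone, and with total counts 3 were higher and 30 lower. Of these, rpsU fell 3.51-fold (log2 -1.81 ± 0.05) and rpmB 1.78-fold (-0.83 ± 0.05). The translation initiation gene infA fell 3.40-fold (-1.76 ± 0.04), on a list with 7 genes higher and 6 lower of 17, and 7 and 7 as adjusted over the list alone (adjusted p = 0.449). Of 50 flagellar and chemotaxis genes, 3 were higher and 15 lower (2 and 15 adjusted over the list alone; adjusted p = 0.449), among them the basal body gene fliE (-1.90 ± 0.18) and the master regulator gene flhD (-0.79 ± 0.07).

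Genes for tRNA formed the group with the most uniform fall. They took 0.222% ± 0.042 of the counts at P5 and 0.702% ± 0.0811 in the STR (SD, n = 16 each), lower in 16 of 16 pairs. The permutation p was 1e-05, the smallest 100000 permutations can give, and 7e-05 adjusted over 7 measures. Of 75 tRNA genes, 65 were lower and 2 higher, with a median log2 difference of -1.31; with total counts 68 were lower and 0 higher. This grouping was chosen after the data were seen. The RNA came from a column kit for longer RNAs, so these counts may not represent mature tRNAs, which are short. Genes for rRNA were higher in 10 of 12 (list adjusted p = 0.316), with a median log2 difference of 1.81. Without P5 at 45 min, replicate 2, the median of the 11 tested was 0.92 and the genes did not pass.

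The next comparison asks where along the loop the differences arose, with P1, P3 and P5 set against the STR at 25 min, 120 min and 28 h. The differences grew along the loop: 33 genes passed at P1, 990 at P3 and 2069 at P5. The leader gene trpL stood at 17.3 ± 3.35 CPM at P1, 79.9 ± 26.2 at P3 and 137 ± 50.3 at P5, against 16.6 ± 3.54 in the STR (SD, n = 6 each). Its log2 difference from the STR was 0.07 at P1 (adjusted p = 0.978), 2.24 at P3 and 3.00 at P5 (SE 0.10 at each). The regulator gene nac differed by 0.00 ± 0.21 at P1 and 0.22 ± 0.21 at P3 (adjusted p = 0.495), and rose by 1.06 ± 0.21 at P5 (adjusted p = 9.62e-05), whereas glnK was higher already at P3 (0.57 ± 0.14, adjusted p = 0.00317).

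The direct tests between ports show the steps. From P1 to P3 trpL rose by 2.17 ± 0.10 and from P3 to P5 by 0.77 ± 0.09 (log2), and mtr rose 2.38-fold and 1.42-fold. For trpE, which was lower at P1 than in the STR (-0.33 ± 0.07, adjusted p = 0.0117) but did not pass there without 120 min, the steps were 0.99 ± 0.07 and 1.12 ± 0.07. The PII gene glnK rose by 0.64 ± 0.14 and then by 0.78 ± 0.14. The steps of nac were 0.22 ± 0.21 (adjusted p = 0.549) and 0.83 ± 0.21 (adjusted p = 0.00349), those of amtB 0.10 ± 0.15 (adjusted p = 0.735) and 0.58 ± 0.15 (adjusted p = 0.00492), and those of glnA 0.35 ± 0.17 (adjusted p = 0.16) and 0.50 ± 0.17 (adjusted p = 0.0256). Whether the steps of a gene differ from each other was not tested. Histidine gene hisG rose in both steps, by 0.47 ± 0.09 and 0.63 ± 0.09. Over both steps udk fell, by 0.90 ± 0.06 and 1.00 ± 0.06, as did rnpA, by 0.83 ± 0.08 and 1.03 ± 0.08. The sigma factor gene rpoS rose from P3 to P5 (0.25 ± 0.07), as did relA (0.27 ± 0.09), and spoT fell (-0.22 ± 0.04). Their steps from P1 to P3 did not pass. Neither gltB, gdhA nor glnG passed in either step.

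**Figure D3:**
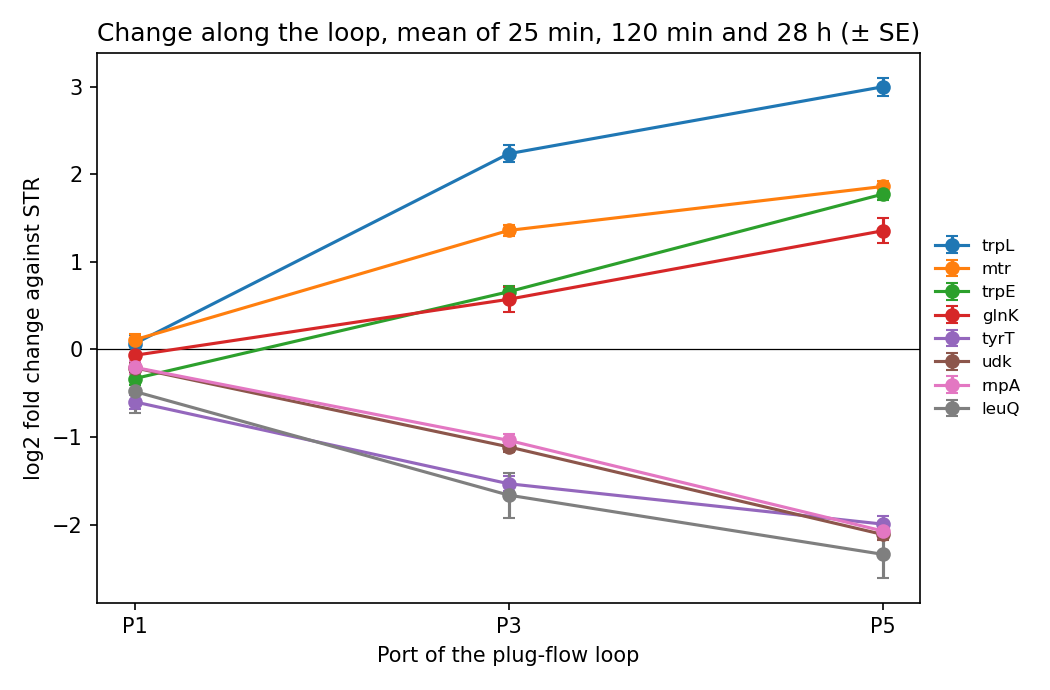
Log2 difference from the STR (vertical axis) at P1, P3 and P5 (horizontal axis) averaged over 25 min, 120 min and 28 h, for genes named by the rule, with bars of 1 SE. The gene trpL lies at 0.07, 2.24 and 3.00, and udk at -0.21, -1.11 and -2.11.

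At P3, 440 genes were higher and 550 lower, and at P5 1043 and 1026. With total counts the splits were 86 and 994 at P3, and 406 and 1455 at P5, with medians moved by -0.11 and -0.13. Between ports, 707 genes differed from P1 to P3 (265 higher, 442 lower; 66 and 646 with total counts), 980 from P3 to P5 (347 and 633; 193 and 721), and 1893 from P1 to P5 (916 and 977; 433 and 1251). Without 120 min the counts were 457, 562 and 1693, and in fits to the libraries of each comparison alone 412, 966 and 1734. At P3 the general stress list passed with 9 of 31 genes higher (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.000281, and adjusted p = 0.66 with an estimated correlation). The pentose phosphate list passed with 7 of 9 higher (8 adjusted over the list alone; adjusted p = 0.000281, and adjusted p = 0.264 with an estimated correlation). The NtrC and Nac list at P3 had 2 higher and 1 lower of 50 (1 and 0 adjusted over the list alone; adjusted p = 0.636). Shares of counts in tRNA genes were 0.666% ± 0.0809 in the STR, 0.559% ± 0.083 at P1, 0.334% ± 0.0577 at P3 and 0.210% ± 0.0453 at P5 (SD, n = 6 each). Of the 75 tRNA genes, 5 were lower at P1, 52 at P3 and 62 at P5. The tyrosine tRNA gene tyrT, a copy pair with tyrV, was lower already at P1 (-0.60 ± 0.08, adjusted p = 6.05e-05).

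Near the inlet, P1 resembled the STR at 2 of the 3 times. At 25 min 0 genes passed in edgeR (77 at an unadjusted p under 0.05) and 0 in DESeq2 (50). At 28 h 1 gene passed (tyrT, -0.76), and at 120 min 208 did, of which 201 were higher. At 120 min genes of growth without oxygen stood out at P1: 26 of 30 were higher, with a median log2 difference of 2.28. Examples, chosen after their values were seen, are the fumarate reductase gene frdA (7.28-fold, log2 2.86 ± 0.37, adjusted p = 3.6e-06), the nitrate reductase gene narG (6.88-fold, 2.78 ± 0.37) and the hydrogenase gene hybA (3.58 ± 0.48). Cold shock genes cspA (1.90 ± 0.40), cspB (2.98 ± 0.56) and cspG (2.25 ± 0.47), the acid-inducible asr (3.32 ± 0.22), the copper exporter gene copA (2.28 ± 0.21) and the periplasmic chaperone gene spy (2.84 ± 0.32) were higher too, also chosen after their values were seen. The libraries differed in size of effect: frdA reached 1647 CPM in replicate 1 and 393 in replicate 2, against 139 and 141 in the STR at that time. The SEs and p-values rest on a spread estimated over all groups, so they do not measure the spread of these 2 libraries alone.

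**Figure D4:**
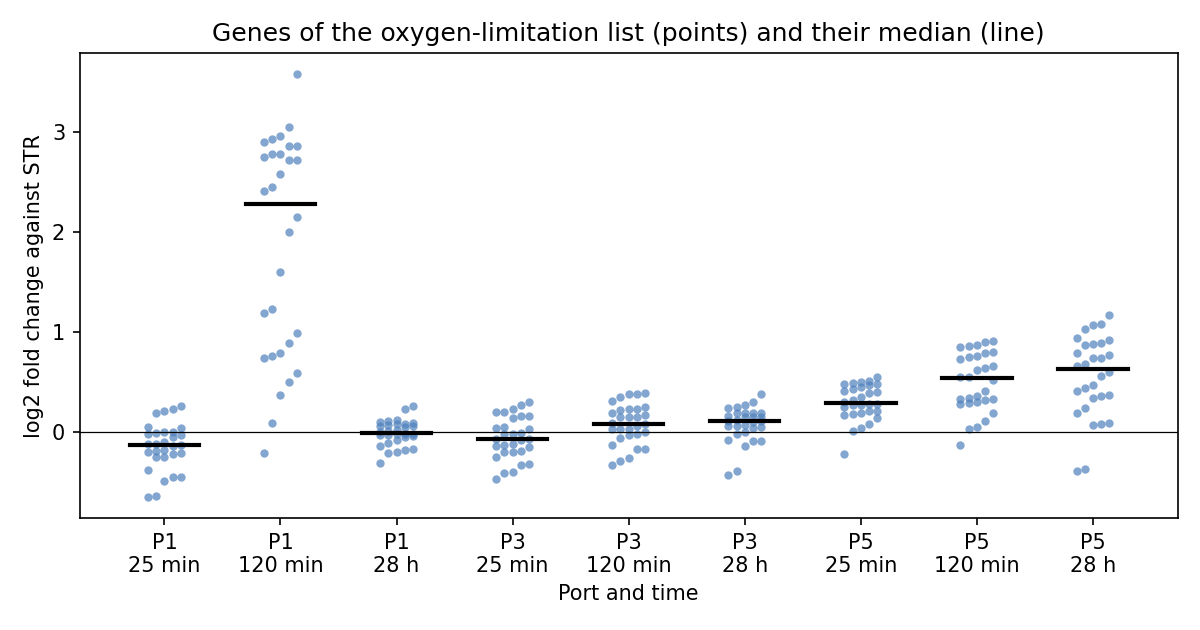
Log2 difference from the STR (vertical axis) of the 30 genes of the oxygen-limitation list at each port and time (horizontal axis), as points, with the median as a line. The median is 2.28 at P1 at 120 min and -0.01 at P1 at 28 h; the largest median at P3 or P5 at 120 min is 0.54.

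The average over 3 times at P1 rests on that time. Of its 33 genes 25 were higher and 8 lower (20 and 33 of 53 with total counts), and without 120 min 1 gene was left, tyrT (-0.58 ± 0.10). Each of the 12 libraries moved the count when left out: to between 5 (without P1 at 28 h, replicate 2) and 14 (without P1 at 25 min, replicate 1) for 11 of them, and to 251 without P1 at 120 min, replicate 2. On average over the 3 times, the oxygen-limitation list was higher in 7 of 30 genes (25 adjusted over the list alone; adjusted p = 6.61e-29, and adjusted p = 0.201 with an estimated correlation). Without 120 min its median was -0.04.

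The STR windows ask how the tank population differed from the reference state after the loop was added. Every reference sampling came before that, so the loop and the age of the culture cannot be told apart here. In the early, middle and late windows 33, 50 and 50 of 50 flagellar genes were higher than in the reference state, 34, 37 and 36 of 50 nitrogen scavenging genes were lower, and 10, 7 and 7 of 11 genes of lysine and threonine synthesis were lower. With an estimated correlation the last of these lists passed in each window, and the others in none (late adjusted p = 0.191 for the flagellar and 0.297 for the nitrogen list with an estimated correlation). The flagellar sigma factor gene fliA stood at 179 ± 98.4 CPM in the reference state (SD, n = 6), 454 ± 248 in the early window (n = 8), 868 ± 180 in the middle window (n = 8) and 596 ± 157 in the late window (n = 6). It rose 2.30-fold (log2 1.21 ± 0.25, adjusted p = 0.000249), 4.99-fold (2.32 ± 0.26) and 3.44-fold (1.78 ± 0.26). The regulator gene nac, at 4367 ± 277 CPM in the reference state, fell 1.88-fold (-0.91 ± 0.19, adjusted p = 0.000402), 2.47-fold (-1.30 ± 0.20) and 2.56-fold (-1.36 ± 0.21). In the early, middle and late windows 1381, 1167 and 957 genes passed.

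**Figure D5:**
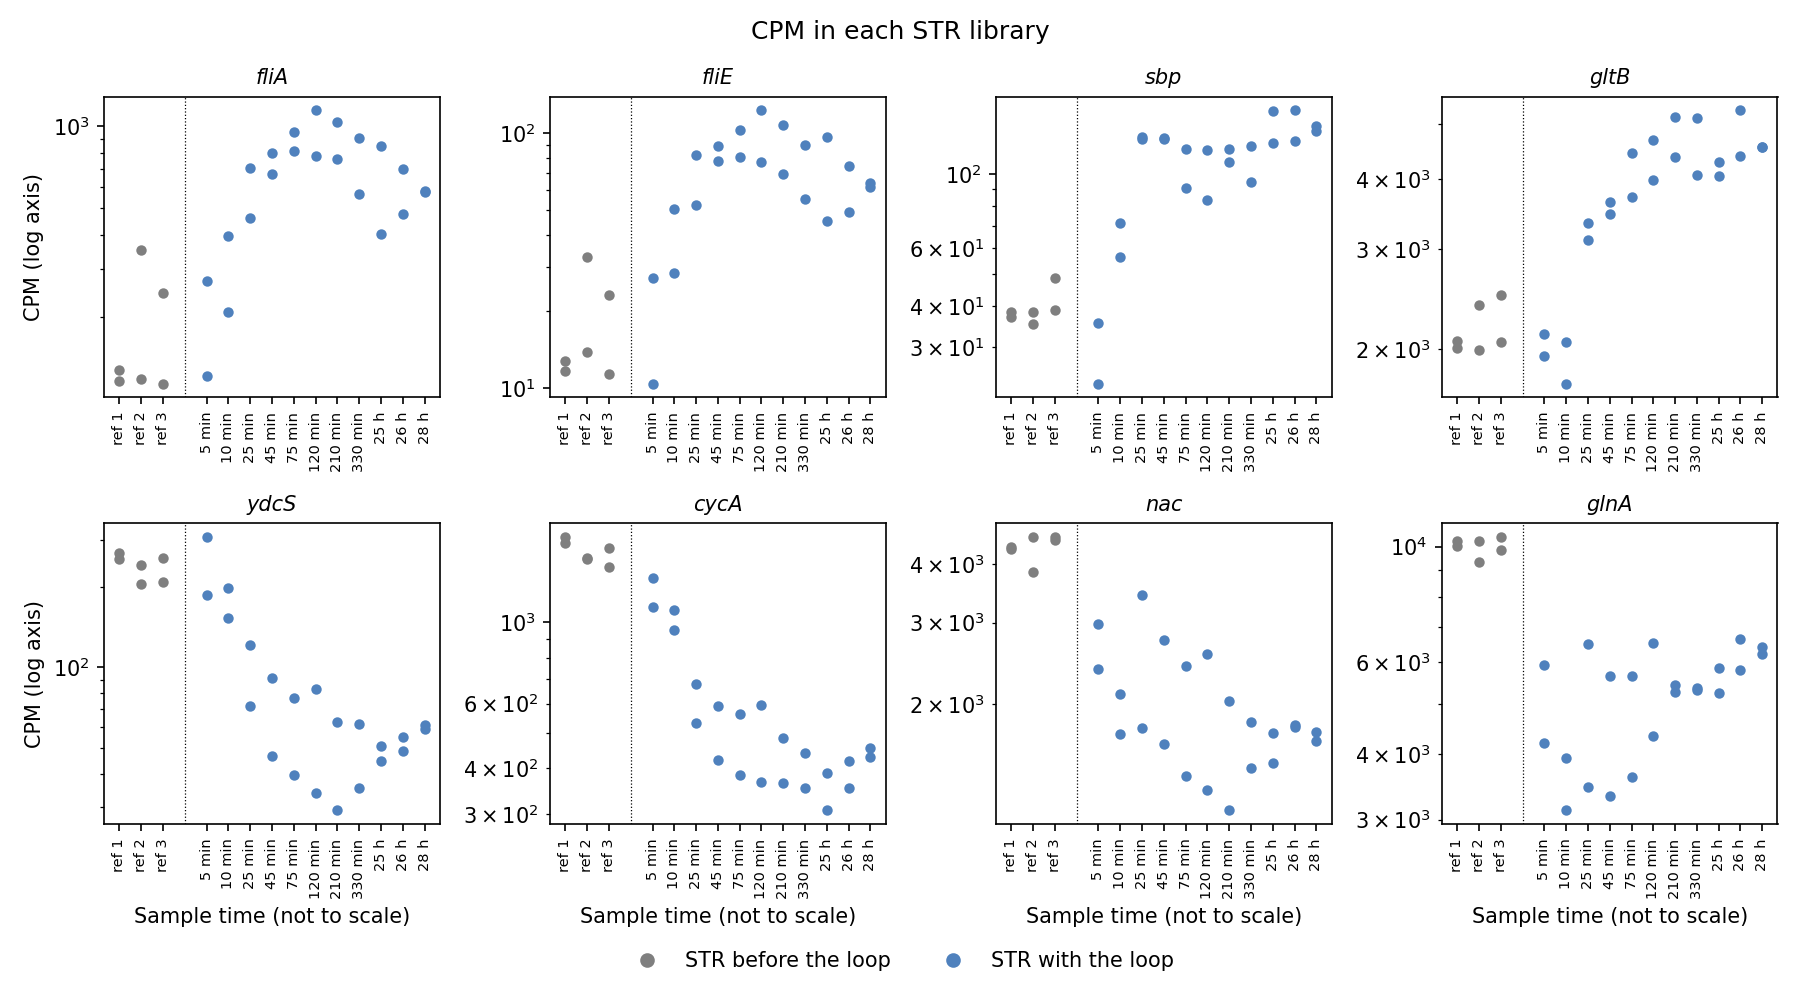
CPM on log axes (vertical) of 8 genes in each STR library by sample time (horizontal axis, not to scale), with reference libraries in grey and libraries after addition of the loop in blue. Means in the late window are 140 CPM for sbp against 39.4 in the reference state, and 392 for cycA against 1555.

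Of 50 flagellar and chemotaxis genes, 33 were higher in the early window, 50 in the middle and 50 in the late window (36, 50 and 50 adjusted over the list alone), with median log2 differences of 0.97, 2.09 and 1.51. The list passed in each (late adjusted p = 4.26e-38), but with an estimated correlation in none (adjusted p = 0.437, 0.106 and 0.191 with an estimated correlation). Flagellin gene fliC differed by 0.25 ± 0.34 in the early window (adjusted p = 0.635) and rose by 2.09 ± 0.36 and 1.32 ± 0.37 in the others. Of the 37 genes for uptake of alternative carbon sources under CRP, 20 were higher early and 21 late (21 and 22 adjusted over the list alone; late adjusted p = 8.15e-09, and adjusted p = 0.191 with an estimated correlation).

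In the NtrC and Nac list 34, 37 and 36 of 50 genes were lower in the 3 windows, and 2 were higher in the late one. Adjusted over the list alone 36, 37 and 40 were lower, and 2, 0 and 2 higher. The list passed in each (late adjusted p = 3.35e-21), and in none with an estimated correlation (adjusted p = 0.437, 0.429 and 0.297 with an estimated correlation). Glutamine synthetase gene glnA fell by 1.16 ± 0.15 early, 0.95 ± 0.15 in the middle and 0.74 ± 0.17 late. The genes glnK and amtB fell early (-0.63 ± 0.13 and -0.59 ± 0.14) and differed by -0.34 ± 0.14 (adjusted p = 0.0839) and -0.32 ± 0.15 (adjusted p = 0.123) late. The late difference of glnG was -0.42 ± 0.16 (adjusted p = 0.0579). In DESeq2 glnK (adjusted p = 0.0488) and glnG (0.0298) passed late, as did glnG with RLE size factors (0.0465). With the replicate number as an added term glnK, amtB and glnG passed late, though these numbers do not pair the libraries throughout. Glutamate synthase genes gltB and gltD rose 2.09-fold (1.06 ± 0.08) and 2.07-fold late, and gdhA fell 1.58-fold (-0.66 ± 0.07). The stringent response gene relA fell by 0.38 ± 0.09, whereas spoT (0.05 ± 0.04, adjusted p = 0.397) and rpoS (-0.09 ± 0.07, adjusted p = 0.384) did not pass.

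Lysine and threonine synthesis was lower in 10, 7 and 7 of 11 genes, the same as adjusted over the list alone, and passed in all 3 windows also with an estimated correlation (adjusted p = 0.0123, 0.0459 and 0.00739 with an estimated correlation). In the late window thrA fell 2.09-fold (-1.06 ± 0.09) and thrB 2.00-fold. Branched-chain synthesis was lower in 10 of 13 genes and higher in 2 late, as adjusted over the list alone (adjusted p = 7.81e-06, and adjusted p = 0.191 with an estimated correlation). Amino acid and peptide transport had 10 genes higher and 12 lower of 31 late, and 14 and 12 adjusted over the list alone (adjusted p = 1.23e-05, and adjusted p = 0.191 with an estimated correlation). Its median was 0.08 and its mean -0.17, and its members include the dipeptide transporter gene dppA (-1.04 ± 0.07) and cycA, for uptake of alanine and glycine (3.98-fold lower, SE 0.14 on the log2 scale, adjusted p = 8.76e-13).

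The largest late rises were 6 flagellar genes led by fliE (1.92 ± 0.29), together with sbp, for a sulfate-binding protein (3.55-fold, 1.83 ± 0.13), asnA (3.39-fold, 1.76 ± 0.25), yecR and yjcZ. Of the largest late falls, 5 belong to the ydc transporter operon, among them ydcT (4.67-fold lower, -2.22 ± 0.25) and ydcS (4.51-fold lower, -2.17 ± 0.29). The others were cycA, guaD, for guanine deaminase (3.08-fold lower, -1.62 ± 0.20), ynfM, ddpA and nac. At single STR times 408 to 1034 genes differed from the reference state, with 601 at 330 min and 957 at 25 h, or 377 and 524 without the 4 libraries in which near-silent genes were raised (replicate 1 of the STR at these times, and of P5 at 120 and 210 min). Of the late genes 505 were higher and 452 lower, against 404 and 518 with RLE size factors, 379 and 500 with DESeq2, and 663 and 319 with total counts. Total counts also turned the balance in the early window (639 and 742, against 774 and 514) and the middle window (492 and 675, against 674 and 477).

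The early window differed from the late one in 1027 genes, 563 of them higher late and 464 lower (421 and 540 with RLE size factors). In the early window set against the reference state, 39 of 54 ribosomal protein genes were higher (45 adjusted over the list alone, median 0.21, adjusted p = 1.8e-08, and adjusted p = 0.437 with an estimated correlation). The arginine synthesis list was higher in 11 of 11, with argB at 0.55 ± 0.08 (adjusted p = 6.78e-09, and adjusted p = 0.32 with an estimated correlation). General stress genes were lower in 20 of 31 (21 adjusted over the list alone; adjusted p = 1.18e-06, and adjusted p = 0.424 with an estimated correlation), and acid resistance genes in 11 of 13 (12 adjusted over the list alone; adjusted p = 0.000104, and adjusted p = 0.437 with an estimated correlation). Among the latter gadA, which shares much of its sequence with gadB, was 2.16-fold lower (-1.11 ± 0.22). Both falls were also seen in the middle window. There 21 of 31 general stress genes and 12 of 13 acid resistance genes were lower and 0 higher. The list adjusted p was 8.79e-08 and 1.77e-13, and 0.406 and 0.153 with an estimated correlation.

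The last comparison asks whether the response at P5 changed over a day: the difference between P5 and STR at 25 h and 28 h was set against that at 5, 10 and 25 min. The genes that were relatively higher in the late response include gpt, which salvages guanine (log2 difference of differences 0.84 ± 0.14, adjusted p = 0.000276), ndk, for nucleoside diphosphate kinase (0.74 ± 0.19), and pyrF of pyrimidine synthesis (0.50 ± 0.09, adjusted p = 0.000536). Each place had 4 late and 6 early libraries. The late STR libraries include replicate 1 at 25 h, in which near-silent genes were raised. The largest rises also held ygaW, now alaE, an alanine exporter gene (1.23 ± 0.36, adjusted p = 0.0325), frdB (1.08 ± 0.32) and ybfE (0.77 ± 0.14). The largest falls were yodB (-0.96 ± 0.14), the copper and silver efflux gene cusA (-0.93 ± 0.27), yhiF, now dctR (-0.88 ± 0.27), appY (-0.86 ± 0.26) and ycdT, now dgcT (-0.82 ± 0.12).

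The difference between the responses did not pass for glnK (0.08 ± 0.23, adjusted p = 0.854) or glnA (0.04 ± 0.26, adjusted p = 0.946). As a list, glutamate assimilation passed toward higher values late (adjusted p = 0.025, and adjusted p = 0.287 with an estimated correlation), with a median log2 difference of 0.15, while none of its 11 genes passed alone, nor adjusted over the list alone. Pyrimidine synthesis was higher in 4 of 11 genes (7 adjusted over the list alone; adjusted p = 1.52e-06) and purine synthesis in 3 of 15 (7 adjusted over the list alone; adjusted p = 8.75e-07), each with an adjusted p = 0.287 with an estimated correlation. Nucleoside and nucleobase scavenging did not pass, with 1 of 22 genes lower (1 adjusted over the list alone; adjusted p = 0.191). Of the 37 lists, 19 passed, each toward higher values late, and none of them with an estimated correlation. Among them translation factors were higher in 3 of 17 genes (6 adjusted over the list alone; adjusted p = 7.35e-06), glycolysis in 5 of 17 (7 adjusted over the list alone; adjusted p = 1.06e-05) and aerobic respiration in 2 of 21 (8 adjusted over the list alone; adjusted p = 1.06e-05), each with an adjusted p = 0.287 with an estimated correlation. In all 300 genes passed, 155 higher and 145 lower, against 221 and 101 with RLE size factors, 259 and 78 with DESeq2, and 63 and 257 with total counts. The count was 574 without the STR at 25 h, replicate 2, and 145 without its replicate 1. It was 173 without the STR at 25 min, replicate 2, and 138 without the STR at 28 h, replicate 2. At P5 it was 167 without 25 h, replicate 1, and 194 or 183 without replicate 1 or 2 at 28 h.

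The 3 reference samplings were set against each other to see whether the steady state moved before the loop was added. In edgeR 0 genes passed, with 43 at an unadjusted p under 0.05; in DESeq2 0 passed, with 29 at an unadjusted p under 0.05. Flagellar gene fliA nevertheless spread widely among the reference libraries (179 ± 98.4 CPM, SD, n = 6), while glnA stood at 10020 ± 391.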

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

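The tests of P1 at 120 min were chosen only after that result was seen.

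The response at P5 differed between the early and the late times in 300 genes, by a test of the difference itself. The response at P1 at 120 min differed from that at 25 min and 28 h in 131 genes, each of them higher at 120 min in edgeR (145 in DESeq2). The same test gave 0 genes at P3 and 0 at P5 in edgeR, with 40 and 118 at an unadjusted p under 0.05, and 0 at both in DESeq2, with 20 and 81. The lone P5 libraries, which enter none of the averages, held trpL at 150 CPM at 75 min (14.5 and 18.1 in the STR libraries), 113 CPM at 330 min (13 and 14) and 102 CPM at 26 h (15.4 and 14.8). In each of these 3 libraries, the 10 largest rises were higher and the 10 largest falls lower than in the STR of that time. Of the 2718 genes that passed on average, 93.2%, 90% and 92.5% had the same sign in them.

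At P1 at 120 min, 26 of 30 genes of growth without oxygen and cspA, cspB and cspG of cold shock were higher than in the STR. Oxygen falling along the loop would raise the oxygen list at least as much further down, but 26 of its 30 genes were lower at P3 than at P1 and 25 at P5 (median log2 differences of -2.13 and -1.73), and each P1 library (2.95 and 0.99 against the STR) lay above each P3 library (0.11 and 0.10) and P5 library (0.58 and 0.39). This holds for 120 min alone. On the mean of 25 min and 28 h, 13 of the 30 genes were higher at P5 than at P1 and 0 lower (median 0.47), the direction that falling oxygen would give. A response of cells at the inlet at every time is argued against by the larger median at P1 at 25 min and 28 h, which was -0.006. Samples that stood cold and without air before fixation would raise cold shock genes as a list. The median of that list was 0.187, yet 3 of its 10 genes, cspA, cspB and cspG, were higher, so the test cannot decide. Also higher were 8 of 21 heat shock genes, which cold alone would not raise, but the effect of missing air on them was not tested. The rise lies in the 2 libraries of 1 port and time, so handling of these samples and a short event in the culture cannot be told apart.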

How the results depend on the processing

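The alternatives without 120 min, without the 4 libraries with raised near-silent genes, without P5 at 45 min, replicate 2, for tRNA and rRNA genes, and total counts for named genes and lists were chosen only after the results were seen. Each of 32 counts of passing genes stayed within 1.5 times its value with RLE size factors, the filtered table, no low count filter, a minimum mean of 10 CPM, and no rRNA or tRNA genes, and 31 did so with DESeq2, where P1 minus STR gave 69. With the replicate number as an added term P1 gave 56, and with total counts 53. With that term the late falls of glnK, amtB and glnG passed (adjusted p = 0.0209, 0.0238 and 0.0084). Over 378 pairs of groups the correlation of replicate 1 minus replicate 2 had a median of 0.15 (-0.58 to 0.83), above 0.1 in 63.2% and under -0.1 in 6.08%: the numbers do not pair the libraries throughout, and an effect shared by part of them stays open. Fitted to the libraries of the comparison alone, P5 minus STR gave 420 at 5 min, 523 at 25 min, 590 at 45 min, 527 at 120 min, 135 at 210 min and 1094 at 25 h, P1 minus STR 1, P3 minus P1 412, and the STR against the reference 622 at 25 h and 793 at 28 h. Without the 4 libraries the STR gave 377 at 330 min and 524 at 25 h. Without 120 min P1 gave 1, P3 minus P1 457 and P5 minus P3 562. With reference 3 alone the windows gave 746, 612 and 452. With 1 library or 1 replicate number left out, where a lone library is assumed to vary like the other groups, P1 gave 0 to 251, P3 356 to 1099, P3 minus P1 195 to 842, P5 minus P3 517 to 1055, the early window 578 to 1410, the middle 669 to 1144, the late 504 to 1012, late minus early 364 to 1025, and the difference between responses 138 to 574. With total counts, P5 minus STR at single times had 95 to 222 genes higher and 815 to 1728 lower. For the difference between responses, that scaling reversed the sign of glnA (-0.052), glnK (-0.009), amtB (-0.056), relA (-0.081), spoT (-0.004) and rpoS (-0.023), none of which passed with either scaling. Of 41 list calls, 41 kept their side with RLE size factors, 39 with the replicate term, 34 with total counts, 31 with fry and 1 with an estimated correlation. The cause of these moves was not tested. On simulated data 14% of the smallest changes were recovered at 25 min, with 2 libraries per place, against 86% with 16 per place; depth was not varied.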

Other observations

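The tests of operons, of tRNA genes as a group, and of place and time for the near-silent genes were chosen only after the results they bear on were seen.

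In the STR, genes for tRNA moved against the direction seen in the loop. They took 0.531% ± 0.0293 of the counts in the reference state (SD, n = 6) and 0.750% ± 0.0758 in the early window (SD, n = 8), and 40 of 75 were higher, with a median log2 difference of 0.43. In the late window 3 were higher and 1 lower. The limit set by the kit for longer RNAs holds for these counts too. In the middle window acid resistance genes were lower in 12 of 13, with the same count adjusted over the list alone and a median of -1.35 (adjusted p = 1.77e-13, and adjusted p = 0.153 with an estimated correlation). The regulatory RNA gene csrB took 2.46% ± 0.506 of the counts at P5 and 2.05% ± 0.325 in the STR (SD, n = 16 each; higher in 11 of 16 pairs; permutation p = 0.0055, adjusted p = 0.013). In P5 at 210 min, replicate 2, the gene ssrA for transfer-messenger RNA took 13% of the counts, the highest share of the 59 libraries.

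Of the genes in the raw table with any count, rRNA and tRNA genes left out, 162 had a median below 1 CPM. CPM is taken here without TMM. Their mean was raised to more than 2 times its median of 0.497 CPM in 4 libraries: STR at 330 min and 25 h, and P5 at 120 min and 210 min, replicate 1 of each. Lower depth is argued against, since 3 of the 4 were above the median total count. Place and time are argued against as well, since the other libraries of these groups reached at most 0.525 CPM. Genomic DNA among the reads might add a like excess to all genes: the ratio of the excess in genes of 3 to 10 CPM to that in the near-silent genes was set beforehand to be at most 2 if DNA was the cause and above 4 in some library if not. The highest ratio was 4.07 (95% bootstrap interval 3.35 to 4.92), just above 4 with an interval that holds 4, and the lowest was 3.41. The lower interval limits of the 4 libraries ran from 2.83 to 3.35, above 2. Being above 2 beyond their intervals, the ratios argue against DNA that adds a like excess to all genes. No library passed 4 beyond its interval, so the test as set beforehand could not decide. Whether an excess that differs by gene length would give such ratios was not tested, so genomic DNA is not excluded.

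A hypothesis was that transcription under way in the loop had not reached the ends of operons, so that the first gene of an operon would change more than the last. Over all 45 operons the first gene changed more in 27 in P5 minus STR (two-sided exact binomial p = 0.233), in 23 in P3 minus STR (exact binomial p = 1) and in 28 in the late STR window (exact binomial p = 0.135); this did not meet the prediction, but most operons moved little at either end and carry little information on it. In a narrower test, set up only after that result and the values of the operons were seen, the first gene changed more in 14 of the 15 operons with either end past 0.5 log2 at P5 (exact binomial p = 0.000977), in 3 of 4 such operons at P3 (exact binomial p = 0.625) and in 10 of 13 late (exact binomial p = 0.0923). The last gene changed less than 0.5 times as much as the first in 14 of these at P5 and in 1 late (Fisher exact p = 8.04e-06). With limits of 0.3 and 0.7 log2 the Fisher exact p was 0.00773 and 0.00109. At 0.5 log2, 5 operons are in both sets. The difference argues against a position effect of the same size in all comparisons. These tests count operons as independent. Operons can move together, as the flagellar and chemotaxis operons fliF, fliL, flgB, mocha and meche did late, so the p-values may be too small. A delay may account for values at P5 such as those of hisG (1.07) and hisI (0.17) or ybgC (-1.07) and pal (0.14), but P3, where cells had spent less time in the loop, has too few such operons to show it; promoters within operons and decay along them were not tested.

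Other splits of the same libraries, 100 drawn with the real one included, were compared by the number of passing genes in fits to those libraries alone. The real split passed more genes than any other for P5 minus STR over 8 times (2605 genes, highest other split 1815), P3 (1193, 32) and P5 (2089, 324) over 3 times, P3 minus P1 (412, 50), P5 minus P3 (966, 534), P5 minus P1 (1734, 607), the early (1385, 65), middle (1493, 750) and late (1225, 3) windows, late minus early (836, 30) and the difference between responses (232, 0). In each, 1 of 100 splits, the real one, gave as many, which argues against a random draw of these libraries. The splits treat libraries as exchangeable, although samples of 1 cultivation over time are repeated samples. Each window also lies wholly after the reference state. A change of the culture with time would exceed such splits too, so this test cannot exclude it. For P1 minus STR 8 of 100 splits gave at least as many as the real 1 gene, with up to 249, so chance is not excluded there, and a split that calls that many points to another structure of these libraries.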
